A study of Mus musculus with 14 samples.

How the data were processed

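RNA from brains of mice heterozygous for the T9H translocation was measured on 14 Affymetrix GeneChip 430A arrays. Per the labels, 8 groups were made of 2 duplications in 4 tissues: neonatal cortex, neonatal cerebellum and 15.5 dpc brain with 2 arrays per duplication, and 13.5 dpc brain with 1 array per duplication. MatDp7 mice carried a maternal duplication of proximal chromosome 7 and a paternal duplication of proximal chromosome 15, and PatDp7 mice carried the reverse. The labels name the replicates biological replicates but give neither animals nor pools, so the p-values measure the spread between samples.

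The deposited values are linear signal intensity, made with MAS5 per the submitters' processing notes, which give no version. The 2% trimmed mean of every array lay between 500.13 and 500.15, so the deposited intensity was taken as already scaled and was used without further scaling. The file holds 22690 probe sets, of which 64 are controls. Of the other 22626, the annotation given names 1 gene for 20380, several genes for 691 and none for 1555.

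Values were changed to log2 after adding 52.0273, the 20th percentile of all values. Probe sets with a mean log2 value at or above the 40th percentile were tested, which left 13576 probe sets and 8156 genes. The limma package 3.58.1 in R 4.3.3 fitted a mean for each of the 8 groups, with an intensity trend in the variance, 6 residual degrees of freedom and 3.15 prior degrees of freedom. Probe sets with a Benjamini-Hochberg adjusted p under 0.05 were called. The 13.5 dpc groups hold 1 array each and add nothing to the spread, so their arrays are assumed to vary like the others. The parental contrast is PatDp7 minus MatDp7 averaged over the 3 replicated tissues, and it was also taken in each tissue. An F-test asked whether the parental difference varied between tissues. Errors of log2 differences are standard errors from limma, and errors of intensities are SD. Intensities given with n = 6 pool 2 arrays from each of the 3 replicated tissues. Their SD therefore also holds differences between tissues, and the 6 arrays are not 6 independent replicates of 1 tissue. Where a group's mean intensity lay under the added constant, the size of the log2 difference is set largely by that constant and is not a measured fold.

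A gene with several probe sets is represented by the probe set with the highest mean log2 value. Before the data were examined, a rule set which genes are named. For parental origin it took the measured members of the chromosome 7 imprinted lists and, in each direction, the 10 genes with the smallest adjusted p. For the other comparisons it took the 10 called genes with the largest log2 difference in each direction, and for each list described up to 4 members with the smallest p. Probe sets with no gene or several genes are given by identifier only where singled out after their values were seen. The 36 gene lists written at the same time were tested with limma camera on 1 probe set per gene, with a preset correlation of 0.01 between genes and, as a second value, an estimated correlation. Lists with fewer than 3 tested members were not tested. Chromosomes and gene order came from the GRCm38.p6 gene table, which the files themselves do not name, so no positions are given. Fisher exact tests were two-sided.

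Samples with the same replicate number were checked for shared deviations from their group means. The correlation was 0.71 to 0.816 in the 6 pairs of neonatal groups and -0.0922 to 0.264 in the other 9 pairs of groups. With 2 numbers only, the labels do not make these pairs, and the fit without a block stayed the reported one. A fit with the replicate number as a block for the 8 neonatal arrays was added after the data were seen, with 5 residual and 6.82 prior degrees of freedom, and its values are printed beside results that it moves.

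The method was tested on simulated data, with 50 probe sets changed at each of 4 sizes among 13576. For the parental mean, 4% were recovered at a log2 change of 0.5, 74% at 1, 94% at 2 and 100% at 4, with 6 false calls among 142. For 15.5 against 13.5 dpc, 20% were recovered at 1 and 80% at 2. Noise was drawn independently for each array, without the deviations shared by the neonatal arrays, so these rates may not hold for the real arrays. Alternatives covered the added constant, the filter, quantile and median scaling, the probe set of each gene, the replicate block and the omission of each of 12 arrays. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9. Detection calls and array images were not used here.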

Results

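The study measured transcripts in brains of mice with a maternal or a paternal duplication of proximal chromosome 7, and the reverse for proximal chromosome 15. Intensities were taken on 14 arrays: 4 of neonatal cortex, 4 of neonatal cerebellum, 4 of 15.5 dpc brain and 2 of 13.5 dpc brain, divided evenly between MatDp7 and PatDp7. Median intensity per array lay between 212.6 and 281.1. The 4 neonatal replicate 1 arrays stood apart, with maximum intensities of 43127 to 61172 against 17662 to 25858 on the other 10. Replicate 1 arrays of the 3 replicated tissues had low Xist, the X-inactivation transcript of female cells, at 198 to 437, and Y-linked Uty at 174 to 319. Replicate 2 arrays and both 13.5 dpc arrays had Xist at 2880 to 5760. Each number holds 1 array of each duplication per tissue, so this split is balanced over the parental comparison, and the labels do not state sex.

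The first comparison asked which transcripts depend on the parent that gave the duplicated segment. Ndn, which encodes the growth suppressor necdin, had an intensity of 103 ± 46.7 (SD, n = 6) in MatDp7 and 12000 ± 1590 (n = 6) in PatDp7, a log2 difference of 6.33 ± 0.208 (limma adjusted p = 2.88e-07). Peg3, a zinc finger gene expressed from the paternal copy, rose from 140 ± 54.7 to 5930 ± 5220, by 4.58 ± 0.395 (adjusted p = 0.000997). Magel2, a neighbour of Ndn that encodes a MAGE family protein, rose by 1.46 ± 0.173, from 157 ± 59.6 to 511 ± 81.9 (adjusted p = 0.0117), a call that ended in 5 of 12 fits that each left out 1 array. Of the paternally expressed list, 4 of 8 genes were tested, and 3 were higher and 1 lower in PatDp7 (camera adjusted p = 2.67e-10, and 0.0145 with an estimated correlation). With the neonatal block the estimated correlation gave an adjusted p = 0.0521.

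The lower member was C230091D08Rik, which has no chromosome in the gene table and whose listing as paternally expressed was not tested for these probe sets. It read 1190 ± 173 in MatDp7 and 329 ± 140 in PatDp7, a log2 difference of -1.77 ± 0.153 (adjusted p = 0.000997, n = 6 and 6). Its other probe set fell by 1.31 (adjusted p = 0.0108), a call that ended in 1 of 12 fits that each left out 1 array. Ube3a, the ubiquitin ligase gene expressed from the maternal copy in neurons, has 4 probe sets, each lower in PatDp7 in 6 of 6 same-numbered pairs. Of these 1 was called, which fell from 463 ± 107 to 159 ± 45.6, a difference of -1.28 ± 0.16 (adjusted p = 0.0164), and this call ended in 8 of 12 fits that each left out 1 array. The representative probe set differed by -2.27 ± 0.667 and did not pass (adjusted p = 1), while with the neonatal replicate block its error was 0.154 and its adjusted p = 6.26e-06. The other 2, under the intensity filter and not tested with the rest, differed by -1.14 and -0.84. Zim3, the other tested member of the maternally expressed list, differed by 0.22 ± 0.247 (adjusted p = 1).

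Uri1, which encodes a prefoldin-like protein, and Pop4, a subunit of ribonuclease P, lie between Peg3 and Ube3a on chromosome 7 and were in no imprinted list. Pop4 went from 484 ± 161 in MatDp7 to 189 ± 34 in PatDp7, a log2 difference of -1.11 ± 0.143 (adjusted p = 0.0194, n = 6 and 6). A Uri1 probe set went from 584 ± 100 to 218 ± 33.8, a difference of -1.23 ± 0.154 (adjusted p = 0.0165). The other 2 Uri1 probe sets, the representative among them, differed by 0.04 ± 0.477 and 0.23 ± 0.288 and did not pass (adjusted p = 1 for each). The Pop4 call and the Uri1 call each ended in 8 of the 12 fits that left out 1 array, and the Pop4 call ended with neonatal replicate 2 alone.

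**Figure D1:**
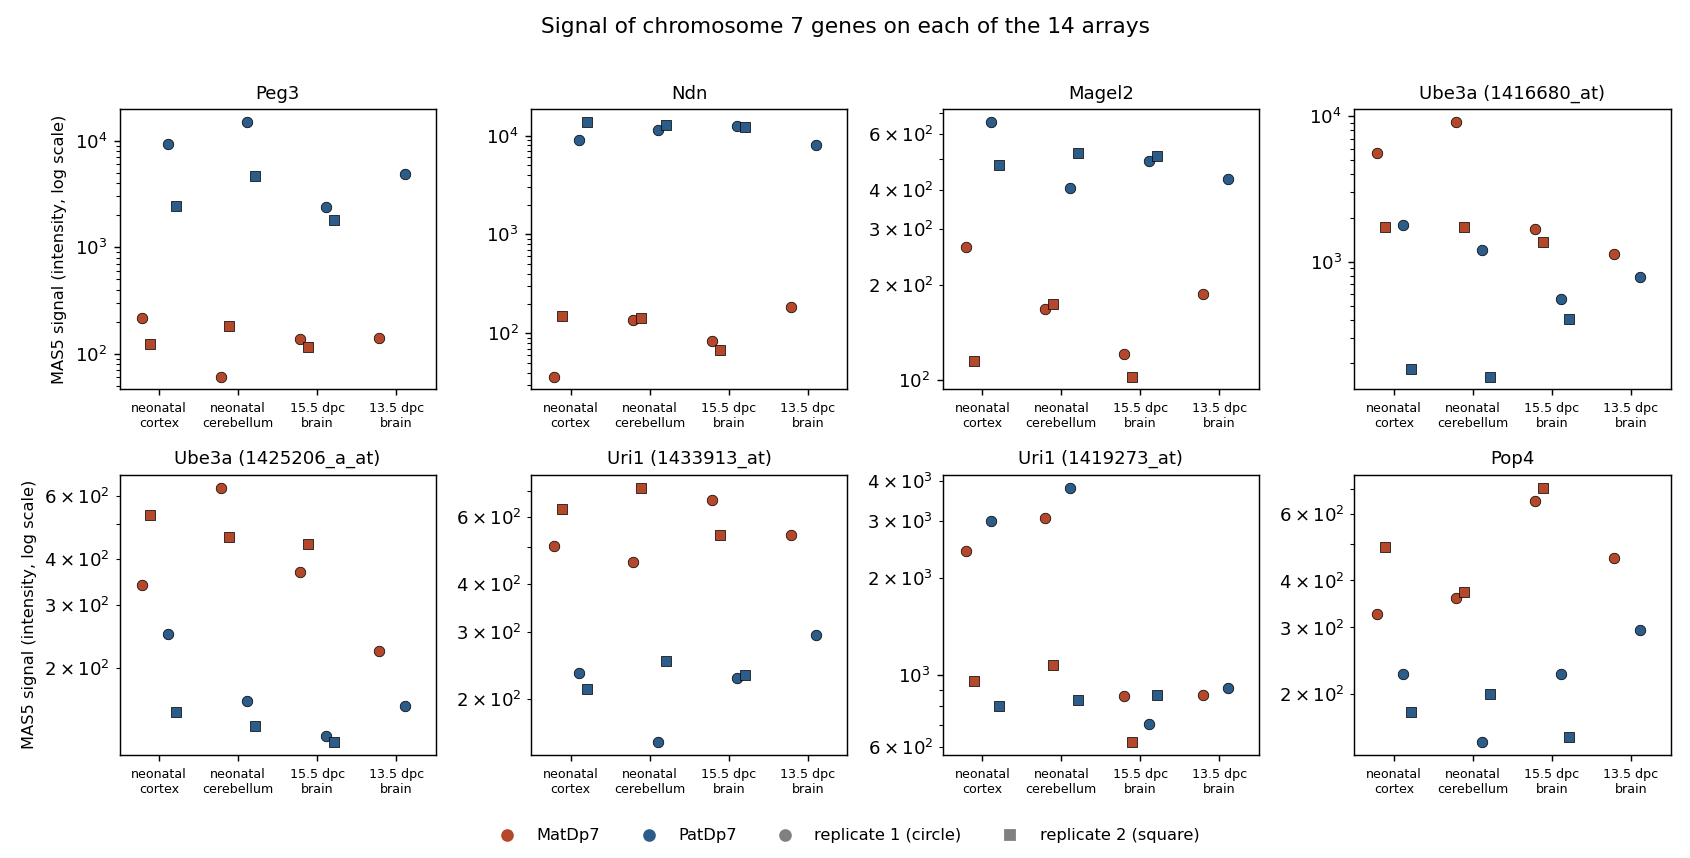
MAS5 signal intensity (log scale) of chromosome 7 genes on each of the 14 arrays, by tissue, with MatDp7 in red, PatDp7 in blue, replicate 1 as circles and replicate 2 as squares. Peg3, Ndn and Magel2 were higher in PatDp7 on every array, while 1 of the 2 Uri1 probe sets shown did not separate the duplications.

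In all, 18 probe sets were called for parental origin, 13 higher and 5 lower in PatDp7, of 13576 tested, and 194 had an unadjusted p under 0.05. Ndn gave 5 of them and Peg3 gave 3. Another 4, annotated to both Snurf and Snrpn, genes of the imprinted Prader-Willi region, were higher by 6.87, 6.54, 5.15 and 2.69. The MatDp7 means of the first 2 were 6.69 and 8.3, under the added constant of 52.0273, so the sizes of these differences depend on that constant. With the neonatal replicate block 26 were called, 13 in each direction, all 18 among them. The 18 kept their sign within replicate 1 and within replicate 2, the arrays that also made the calls. Among 100 splits within the tissues, 7 gave at least 18 calls, the real one included, so chance is not excluded without the block. The highest other split gave 4963, and the 6 others all part both neonatal regions by replicate number. With the neonatal block the real split gave 26 and the highest other of 88 gave 17.

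Below the intensity filter, a fit on all probe sets gave higher PatDp7 signal for 3 more imprinted genes, whose MatDp7 means lay under the added constant, so that the sizes of the differences depend on it. Usp29, a ubiquitin protease gene beside Peg3, differed by 3.25 ± 0.13 (16.4 against 610, adjusted p = 1.85e-06). Its other probe set differed by 0.476 ± 0.221 (109 against 165) and did not pass. Mkrn3, a ring finger gene of the Prader-Willi region, differed by 3.60 ± 0.277 (2.77 against 675, adjusted p = 0.000522), and a probe set of Snrpn alone by 2.17 ± 0.165 (13.1 against 249, adjusted p = 5e-04). Peg12 differed by 0.63 ± 0.101 (1.58 against 32.3, adjusted p = 0.103) and was higher in PatDp7 in 6 of 6 same-numbered pairs. Both its means lay under the added constant, so this size too depends on it. Zim1 differed by -0.52 ± 0.159 (adjusted p = 1) and Atp10a by 0.08 ± 0.0761 (4.06 against 7.51, adjusted p = 1).

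Of the 8150 tested genes with a known chromosome, 6 were called, and all 6 lay on chromosome 7, which holds 589 (7.23%) of the genes tested (Fisher exact p = 1.39e-07). No gene on chromosome 15 was called among 319. With the neonatal block 7 of 9 lay on chromosome 7 (Fisher exact p = 3.15e-07) and 1 on chromosome 15, Ywhaz, a 14-3-3 protein gene. Of its probe sets 1 differed by -1.15 (adjusted p = 0.000667 with the block), while its 6 other probe sets lay between -0.41 and 0.41. The block also called Nudt19 on chromosome 7 (-0.66, adjusted p = 0.0323) and Tcim on chromosome 8 (-0.71, adjusted p = 0.0331).

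**Figure D2:**
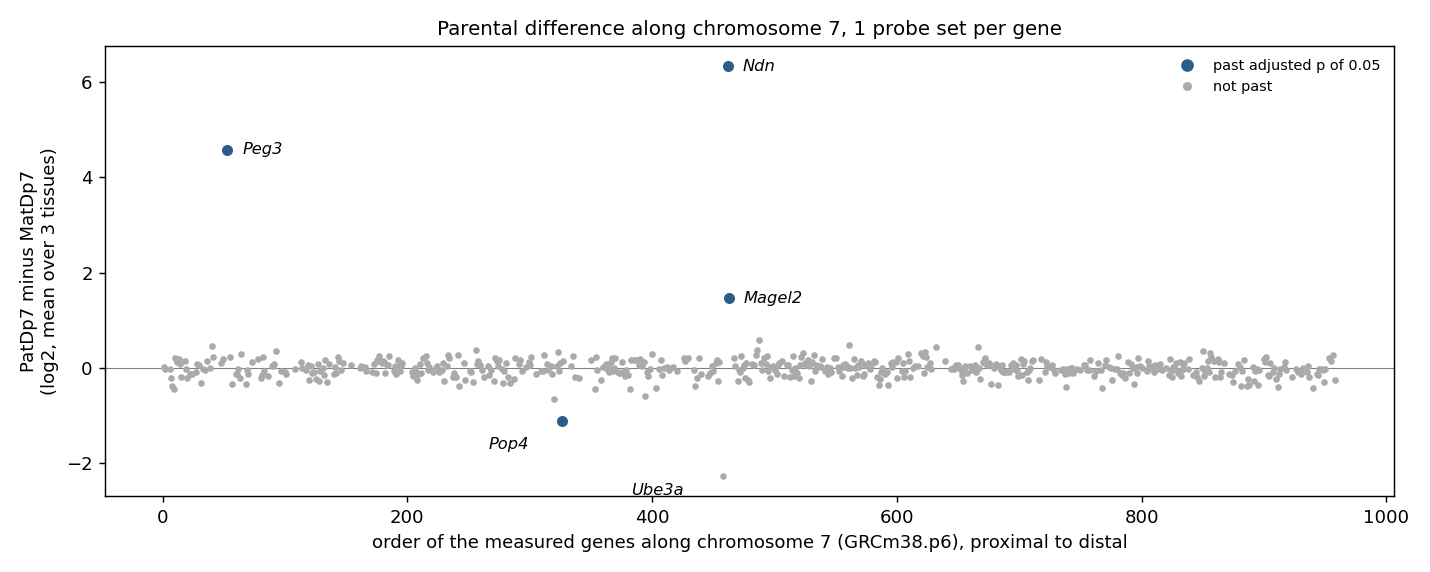
Log2 difference of PatDp7 minus MatDp7, averaged over 3 tissues, for 1 probe set per gene in gene order along chromosome 7 from proximal to distal, with called genes in blue. Peg3, Ndn and Magel2 lie above 0 and Pop4 below, while the Ube3a probe set shown did not pass without the block.

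Genes beside the imprinted clusters gave no call: 0 of 11 tested neighbours passed, among them Herc2, a ubiquitin ligase gene next to Oca2 (-0.27 ± 0.193, adjusted p = 1), and Nipa2, a magnesium transporter gene (0.16 ± 0.128, adjusted p = 1). Imprinted genes of distal chromosome 7 gave 0 of 9, with Cdkn1c, a cell cycle inhibitor gene, at -0.43 ± 0.24. Those of chromosome 15 gave 0 of 2 and those of other chromosomes 0 of 24. The self-test recovered 4% of log2 changes of 0.5, so small differences at these genes are not excluded.

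Among the cell type and stress lists, 5 shifted lower in PatDp7 with the preset correlation, with 0 members called, also when adjusted over the list alone. Telencephalic interneuron and striatal genes had a median of -0.20 (camera adjusted p = 0.00158, adjusted p = 0.446 with an estimated correlation), with Penk, the enkephalin precursor, at -0.58 ± 0.196. Meningeal genes had -0.25 (0.00158, adjusted p = 0.721 with an estimated correlation), with the collagen gene Col1a1 at -0.81 ± 0.395. Immediate early genes had -0.19 and hypoxia genes -0.20 (0.00282 each, adjusted p = 0.446 with an estimated correlation for each). Oxidative phosphorylation genes had -0.13 (0.00616, adjusted p = 0.721 with an estimated correlation). Hypothalamic neuropeptide genes, with a median of -0.139, passed with the neonatal block only (camera adjusted p = 0.0134, against 0.0567 without it). With the block and an estimated correlation they did not pass (camera adjusted p = 0.454).

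Within single tissues Ndn, Peg3 and the Snurf and Snrpn probe sets gave most calls. Ndn differed by 6.39 ± 0.352 in neonatal cortex, 5.99 ± 0.352 in cerebellum and 6.61 ± 0.352 in 15.5 dpc brain (limma adjusted p = 4.16e-05, 5.73e-05 and 3.58e-05; n = 2 and 2 in each). The representative probe set of Peg3 differed by 4.46, 5.70 and 3.58, each ± 0.678, and passed in cerebellum alone (adjusted p = 0.123, 0.0161 and 0.49), while a second one passed in all 3 tissues (5.42, 6.15 and 5.23, each ± 0.297; adjusted p = 4.16e-05, 1.98e-05 and 4.46e-05). The MatDp7 mean of that second probe set, 51.2, lay under the added constant. In cortex 10 probe sets were called, all higher in PatDp7, with 268 at an unadjusted p under 0.05, and 18 with the neonatal replicate block (12 higher, 6 lower). Without cortex PatDp7 replicate 2 the cortex count was 16. In cerebellum 15 were called (11 higher, 4 lower), with C230091D08Rik at -2.33 ± 0.263 (adjusted p = 0.0113), and 21 with the block (12 higher, 9 lower). In 15.5 dpc brain 10 were called, all higher, and 15 with the block (13 higher, 2 lower).

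Whether the parental difference varied between the 3 tissues was asked with an F-test, and 0 probe sets passed, with 67 at an unadjusted p under 0.05. With the neonatal block 3 passed, each at an adjusted p = 0.0484. Among them Elp2, a subunit of the elongator complex, differed by -1.45 in cortex, 0.996 in cerebellum and -0.04 in 15.5 dpc brain, each ± 0.207. The 2 others have no gene in the annotation: the first differed by -2.61, -3.53 and 0.42 and the second by -1.60, -2.77 and 0.76 in the same order.

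The 13.5 dpc pair, with 1 array per duplication and no test, gave values for the same genes. Ndn read 186 in MatDp7 and 8070 in PatDp7, a difference of 5.09, and Peg3 differed by 4.67. Magel2 differed by 1.02 and Pop4 by -0.56. Ube3a differed by -0.50 at its representative and -0.40 at its called probe set. Uri1 differed by -0.77 at its called probe set and by 0.07 and 0.06 at the 2 others. All 18 called probe sets had the same sign in this pair, against 43.7% (5938 of 13576) of all tested probe sets. With the neonatal block the share was 21 of 26.

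Neonatal cortex and cerebellum were compared over both duplications, 4 arrays against 4. Dlx1, a homeobox gene of forebrain interneurons, had mean intensities of 960 (MatDp7) and 751 (PatDp7) in cortex against 9.27 and 4.99 in cerebellum (log2 3.93 ± 0.217, limma adjusted p = 0.000213), a difference whose size depends on the added constant. Dlx2 rose by 2.83 ± 0.259 (0.00228), Dlx5 by 2.60 ± 0.278 (0.00428) and Lhx6, a LIM homeobox gene of the same lineage, by 2.76 ± 0.2 (0.000521). Of 16 tested interneuron and striatal genes 5 were higher, and 7 when adjusted over the list alone (camera adjusted p = 1.66e-09, and 0.0492 with an estimated correlation). With the neonatal block and an estimated correlation the adjusted p = 0.226. Mef2c and Neurod6, transcription factor genes of cortical excitatory neurons, rose by 3.23 ± 0.223 (0.000435) and 2.61 ± 0.265 (0.00369). They were the 2 called of 12 cortical glutamatergic genes, with 5 when adjusted over the list alone (camera adjusted p = 2.44e-08, and 0.0206 with an estimated correlation). Sla, Zbtb18, Cdca7 and the vasopressin gene Avp were higher by 1.97, 1.75, 1.40 and 2.34. Avp was the 1 called of 13 neuropeptide genes (camera adjusted p = 0.00584, adjusted p = 0.282 with an estimated correlation).

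Cerebellum was higher for genes of hindbrain identity. Irx2, Irx3 and Irx5, homeobox genes of the Iroquois family, differed by -2.36 ± 0.242, -2.28 ± 0.274 and -2.02 ± 0.257 (limma adjusted p = 0.00369, 0.00807 and 0.0111). They were 3 of 6 tested hindbrain genes, and 4 passed when adjusted over the list alone (camera adjusted p = 7.71e-10, and 0.0362 with an estimated correlation). En2, a homeobox gene of the midbrain and cerebellum, differed by -2.11 ± 0.274 (0.0123) and was 1 of 10 Purkinje list genes called, with 5 when adjusted over the list alone (camera adjusted p = 3.78e-07, and 0.0206 with an estimated correlation). Meis1 and Barhl1, transcription factor genes of granule cell precursors, differed by -2.46 ± 0.273 and -1.75 ± 0.267 (0.00492 and 0.0289), while the granule cell list did not pass (camera adjusted p = 0.0569). Dlx5 and Cdca7 in cerebellum and En2 and Meis1 in cortex also had a group mean under the added constant. Mab21l1, Ebf3 and Tal1 differed by -2.75, -2.19 and -2.11, and Slc17a6, a vesicular glutamate transporter gene, by -1.56 ± 0.169 (0.00428).

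In this comparison 50 probe sets were called, 30 higher and 20 lower in cortex, and 465 with the neonatal replicate block (231 higher, 234 lower), the 50 among them. The count was 29 and 33 without cortex MatDp7 replicate 1 and 2, 31 and 32 without cerebellum MatDp7 replicate 1 and 2, and 32 without cerebellum PatDp7 replicate 1. In a 2-group fit of the 8 arrays, 2 of 35 splits gave at least the 59 calls of the real one, so chance is not excluded without the block. The highest other split was the one by replicate number, with 4911, and with the replicate number as a block the real split gave 529 and the highest other 24.

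**Figure D3:**
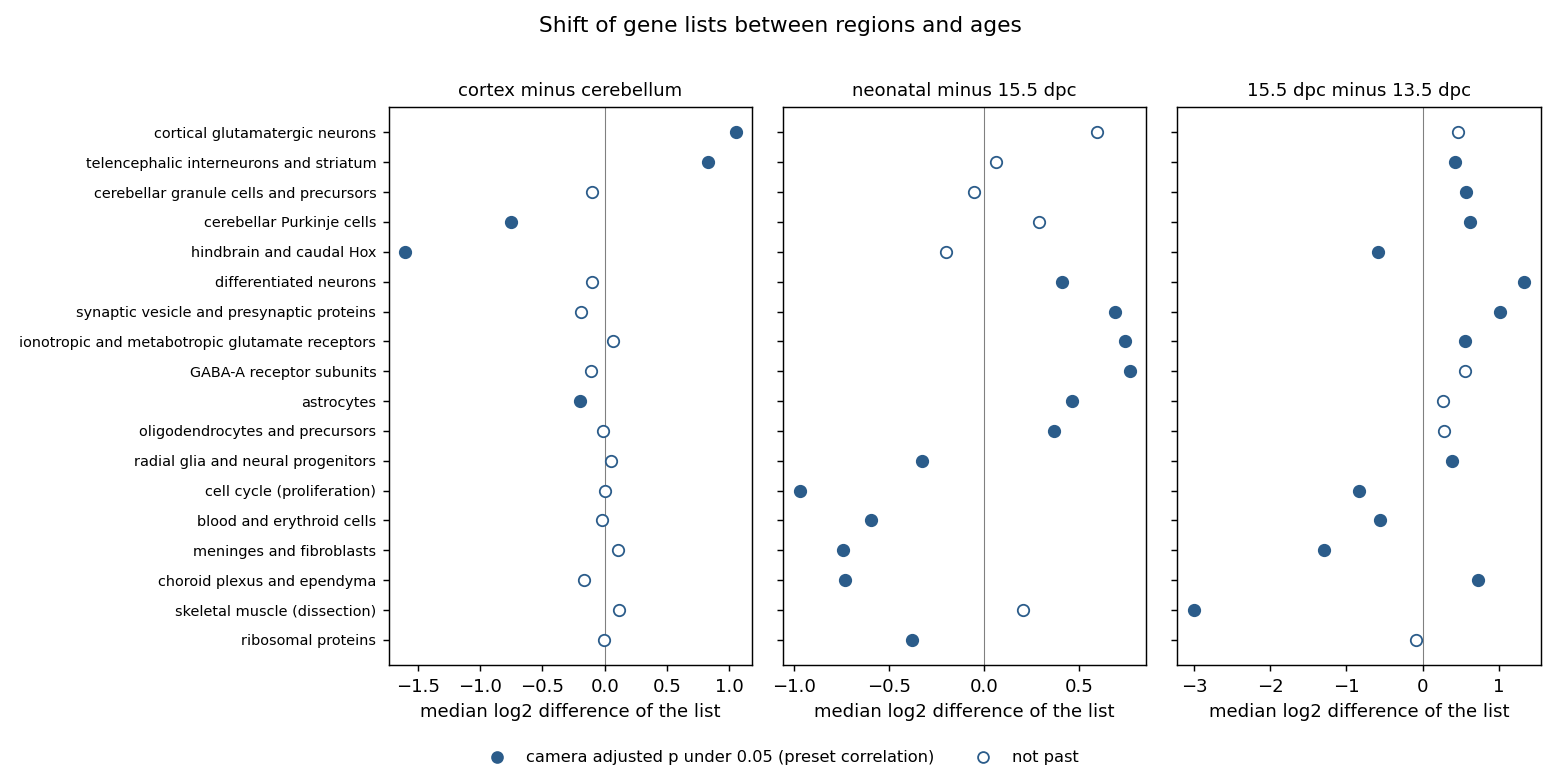
Median log2 difference of 18 gene lists in 3 comparisons of region and age, with filled points where camera passed with the preset correlation. Cortical and interneuron genes lie above 0 in cortex, and cell cycle genes lie below 0 with age in both age comparisons.

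The neonatal regions were compared with 15.5 dpc brain, 8 arrays against 4, where age and brain part differ together. Hbb-y and Hba-x, embryonic globin genes, differed by -4.74 ± 0.369 and -2.49 ± 0.375 (limma adjusted p = 0.00252 and 0.0075). Neonatal Hbb-y means were 1.65 to 2.96 against 1070 and 2580 at 15.5 dpc, and Hba-x, Neurog2 and Omg also had group means under the added constant, so the sizes of these differences depend on it. In the blood list 4 of 11 blood genes were lower (camera adjusted p = 0.012, adjusted p = 0.176 with an estimated correlation). Cell cycle genes were lower for 23 of 33, and 27 when adjusted over the list alone, among them the replication genes Mcm3 (-1.38 ± 0.148, 0.00365) and Mcm7 (-1.21 ± 0.116, 0.00337) and the mitotic kinase gene Cdk1 (-1.93 ± 0.364, 0.0158). That list had a camera adjusted p = 1.93e-14 (adjusted p = 0.176 with an estimated correlation). Neurog2, a proneural factor of progenitors, differed by -1.93 ± 0.259 (0.00562), and 6 of 19 progenitor genes were lower (camera adjusted p = 0.0126, adjusted p = 0.516 with an estimated correlation). Mest, an imprinted gene of chromosome 6, differed by -1.92 ± 0.144 (0.00252). Immp1l, Cd248 and Bub1b differed by -2.08, -1.94 and -1.94, and Cd248 also had a group mean under the added constant.

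Some genes known from neurons and glia were among those called higher in the neonatal arrays, though 0 of 33 lists passed with an estimated correlation. Scn2a, a sodium channel gene, rose by 3.01 ± 0.658 (limma adjusted p = 0.0233), Cntn1, a neuronal adhesion gene, by 2.99 ± 0.536 (0.0136) and Omg, a myelin glycoprotein gene, by 2.55 ± 0.307 (0.00419). Klf9, Tmod2, Camk2g, Caln1, Ncald and Crim1 rose by 2.88, 2.46, 2.36, 2.36, 2.27 and 2.24. The 2 neonatal replicates differed widely for several of these genes, so the sizes of their rises are uncertain. In cerebellum MatDp7, Scn2a read 3200 ± 3330 (SD, n = 2), Cntn1 11900 ± 9970 and Camk2g 8900 ± 7930, while Omg varied less, at 838 ± 195. Synaptic vesicle genes were higher for 7 of 16, with Syn2 at 1.68 ± 0.239 and Sv2a at 1.69 ± 0.335 (camera adjusted p = 3.55e-06, adjusted p = 0.176 with an estimated correlation). Glutamate receptor genes were higher for 3 of 7, with Gria3 at 0.74 ± 0.139 (0.000266, adjusted p = 0.176 with an estimated correlation). GABA-A receptor genes were higher for 3 of 6, with Gabra3 at 0.78 ± 0.19 (0.0034, adjusted p = 0.176 with an estimated correlation). Differentiated neuron genes were higher for 3 of 18 (0.000211, adjusted p = 0.408 with an estimated correlation), and oligodendrocyte genes higher for 2 of 11 and lower for 1 (0.0126, adjusted p = 0.176 with an estimated correlation). Astrocyte genes were higher for 4 of 18, led by the water channel gene Aqp4 at 2.72 ± 0.458 (0.00246, adjusted p = 0.408 with an estimated correlation). Meningeal genes were lower for 5 of 20, with the proteoglycan gene Lum at -2.01 ± 0.204 (0.000211, adjusted p = 0.466 with an estimated correlation). Choroid plexus genes were lower for 3 of 10, with Kcne2 at -1.97 ± 0.194 (0.00502, adjusted p = 0.408 with an estimated correlation).

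Here 1530 probe sets were called, 555 higher and 975 lower, and 5831 with the neonatal replicate block (2682 higher, 3149 lower). The 1530 kept their sign within replicate 1 and within replicate 2, the arrays that also made the calls. In a 2-group fit, 2 of all 495 splits of the 12 arrays gave at least 2753 calls: the real one, and the neonatal replicate 1 arrays against the other 8, with 5561. By this test alone the count is not told apart from the structure of the neonatal arrays. With the neonatal replicate block all 1530 stayed called. That block is balanced within each neonatal group and leaves the log2 differences unchanged, so the signs could not differ. In the split test with this block, the real split and the replicate 1 split fit the same means. Both then compare the neonatal replicate 1 arrays with 15.5 dpc brain. Their counts, 6679 each, had to be equal, so that test cannot tell them apart. With the neonatal replicate 2 arrays only, all 1530 had the same sign, but those arrays also made the calls. The count was 920 without cortex MatDp7 replicate 1, 886 without cerebellum MatDp7 replicate 1, 179 and 676 without 15.5 dpc MatDp7 replicate 1 and 2, and 263 and 177 without 15.5 dpc PatDp7 replicate 1 and 2.

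The 15.5 and 13.5 dpc brains were compared, 4 arrays against 2, where any difference in the tissue taken cannot be told apart from age. Tubb3, a neuronal tubulin gene, was higher at 15.5 dpc by 1.60 ± 0.185 (limma adjusted p = 0.00412), Stmn2 by 1.04 ± 0.16 (0.0095) and Map2 by 1.36 ± 0.228 (0.0137). They were among 7 of 18 neuronal genes, with 11 when adjusted over the list alone (camera adjusted p = 1.6e-08, adjusted p = 0.221 with an estimated correlation). Snap25, a presynaptic fusion protein gene, rose by 1.87 ± 0.366 (0.0235), and 3 of 16 synaptic genes were higher (camera adjusted p = 9.13e-07, adjusted p = 0.183 with an estimated correlation). Gad1, a GABA synthesis enzyme gene, and Sst, the somatostatin gene, rose by 1.96 ± 0.393 (0.0265) and 2.01 ± 0.349 (0.0154), and Olig1, an oligodendrocyte lineage factor, by 2.01 ± 0.281 (0.00731). Rab3b, Slc4a10, B4galnt1 and Hcn3 were higher by 2.74, 2.42, 2.27 and 1.95, with 13.5 dpc means under the added constant in at least 1 group. Mmd2, Neurod6 and Pcp4 were higher by 2.24, 2.11 and 2.06.

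Cell cycle genes were lower at 15.5 dpc for 12 of 33, and 23 when adjusted over the list alone, with Mcm4 at -1.32 ± 0.174 (limma adjusted p = 0.00641). The list had a camera adjusted p = 7.65e-14 (adjusted p = 0.183 with an estimated correlation). The embryonic globin genes Hba-x and Hbb-y differed by -4.58 ± 0.53 and -3.06 ± 0.522 (0.00412 and 0.0148), the 2 called of 11 blood genes (camera adjusted p = 0.01, adjusted p = 0.183 with an estimated correlation). Hmga2, a chromatin gene of early embryos, differed by -3.42 ± 0.454 (0.00656). Smoc2, Cxcl14 and Twist2 differed by -3.4, -3.09 and -3.07. Others called lower at 15.5 dpc, with no list of lens genes tested, were the muscle actin genes Actc1 and Acta1 at -3.80 ± 0.274 and -3.07 ± 0.377, the lens crystallin genes Crybb1 and Crybb3 at -3.86 ± 0.348 and -3.37 ± 0.326, and the fibroblast gene Postn at -2.61 ± 0.283 (0.000424, 0.00509, 0.00164, 0.00191 and 0.00338). Muscle genes were lower for 3 of 5 (camera adjusted p = 1.93e-05, adjusted p = 0.25 with an estimated correlation) and meningeal genes for 5 of 20 (1.71e-06, adjusted p = 0.297 with an estimated correlation). In all 684 probe sets were called, 310 higher and 374 lower, and 2824 with the neonatal replicate block (1596 higher, 1228 lower). The count was 408 and 228 without 15.5 dpc MatDp7 replicate 1 and 2, and 174 and 278 without 15.5 dpc PatDp7 replicate 1 and 2. The spread at 13.5 dpc rests on the other groups, and both 13.5 dpc arrays lacked Y-linked signal while 2 of the 4 at 15.5 dpc had it.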

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

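The tests of sex, scanning, neonatal batch, linked variants and misread probe sets, and the count over all 495 splits, were chosen only after the results were seen. Each tissue with 4 arrays was checked on 5 array measures for a value far from the others, which made 15 checks. Measures of the same arrays are not independent. Of the 15 checks, 3 picked out a value, and about 1 in 20 would by chance. These were the Gapdh 3'/5' ratio of neonatal cortex MatDp7 replicate 1 (0.756), the Actb 3' intensity of 15.5 dpc MatDp7 replicate 2 (5406) and its Actb 3'/5' ratio (1.45). A difference between tissues in the parental effect was found with the neonatal block for Elp2 and for 2 probe sets with no gene in the annotation (limma adjusted p = 0.0484 for each).

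Neonatal replicate 1 and 2 arrays differed by over 1 log2 in 1401 of 13166 autosomal probe sets (10.6%). Of these, 54 did so in the same direction at 15.5 dpc, where 115 probe sets differed by that much. A sex effect alike at both ages does not account for most of it. The replicate differences of neonatal and 15.5 dpc arrays, which both split by Xist, correlated at 0.135. A sex effect in neonatal arrays alone cannot be told apart from the replicate number, since Xist splits along it. Control transcripts added to the hybridisation, which no animal makes, differed by a median of 0.894 log2 over the 4 neonatal groups, against 0.194 and 0.0235 at 15.5 dpc, so scanning or scaling is a candidate explanation. Which of these steps differed was not tested, and a sex effect alike at both ages was the one biological explanation tested.

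In neonatal arrays with the replicate block, 5 probe sets with no gene in the annotation were called, 4 at -2.18 to -3.07 in PatDp7 minus MatDp7 (limma adjusted p = 0.00714, 0.0127, 0.0151 and 0.127 without the block) and 1 at -0.92 (adjusted p = 1 without it), as were Slc2a1, a glucose transporter gene (-0.92), Tcim (-0.86) and Glo1 (-0.70), with adjusted p = 0.309, 0.479 and 1 without the block, while the representative probe set of Slc2a1 differed by -0.56 (adjusted p = 0.241 with the block). The replicate number does not account for the first 4, since each number holds both duplications in both regions. Their limma adjusted p with the block, which takes the number out, was 2.07e-05 to 0.000202. PatDp7 was lower in 16 of 16 same-numbered pairs (the same 4 array pairs for each probe set). Both of these follow largely from the choice of the 4 by this fit and are not counted. Slc2a1, Tcim and Glo1 are not in the glucocorticoid list, of which 16 of 20 genes were lower in PatDp7, with a median of -0.248 (limma camera adjusted p = 2.61e-06 over the 3 lists tried, adjusted p = 0.00906 with an estimated correlation) and 0 called, so a glucocorticoid response in MatDp7 is a candidate explanation for the shift of that list alone. The idea came after the top genes had been seen, 6 of the 20 genes are in other lists, and the other 14, checked afterwards, had a median of -0.186. More blood vessel RNA stays open: the endothelial median of -0.112 met the limit of 0.15 set in advance for no shift, but lay less than the SD of members, 0.273, from the -0.3 that would show more, a condition added after the value was seen, and the blood list did not pass (limma camera adjusted p = 0.336).

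Uri1 and Pop4 were called on chromosome 7 outside the imprinted lists. Linked variants on the duplicated segments may play a part: in the fit with the neonatal block, 6 of 21 genes with p under 0.001 lay on chromosomes 7 and 15 (28.6%, against 11% of others, Fisher exact p = 0.0222). Without the block 2 of 4 did, Uri1 and Pop4 (Fisher exact p = 0.0623), and whole chromosomes were counted because the ends of the duplicated segments are not given. Without Uri1 and Pop4 the blocked count was 4 of 19 (Fisher exact p = 0.148), a check added after the first value was seen, so the question stays open, also against imprinting not in the lists. A misread probe set could account for Uri1, whose other probe sets had a median of 0.134, but Pop4 has 1 probe set and gives no such test.

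Whether arbitrary groupings give as many calls was tested by other splits of the arrays: 7 of 100 reached the parental count, 2 of 35 the cortex against cerebellum count and 1 of 100 drawn the neonatal against 15.5 dpc count, the real split included in each. Of all 495 splits of the last, 2 reached it, and the other one, neonatal replicate 1 against the other 8 arrays, gave 5561 calls against the real 2753, which points to the structure of the neonatal arrays. The highest others were 4963 against the real 18 and 4911 against the real 59, both along the replicate number.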

How the results depend on the processing

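The neonatal block, the block for neonatal and embryonic arrays and the fit on neonatal replicate 2 alone were chosen after seeing the data. Of the alternatives for counts and shares, 221 stayed the same and 55 moved. To stay the same, a count had to lie within 1.5 times the reported one. The 13.5 dpc share had to lie within its binomial confidence interval, and the chromosome 7 share had to keep a Fisher exact p under 0.05. The 208 single-gene values include some that were not called. Of 5024 alternatives for them, 4389 kept their status, called or not called. A call was lost in 594 and gained in 41, and a called value changed sign in 0. The parental mean (18) gave 5 with the mean over probe sets and 28 with both blocks. Cortex (10) gave 6 with an added constant of 1, 4 without _x_ and _s_ probe sets, 2 with the gene mean, 18 with the neonatal block and 20 with both. Cerebellum (15) gave 6 without _x_ and _s_ probe sets and 3 with the gene mean. The 15.5 dpc brain (10) gave 6, 4 and 2 with these 3 changes and 19 with both blocks. The interaction (0) gave 3 with the neonatal block and 3 with both. Cortex against cerebellum (50) gave 33 with the 60th percentile filter, 119 with the replicate block of all arrays, 130 with the additive fit, 722 with the 8 neonatal arrays blocked alone, 465 with the neonatal block and 601 with both. Median centring gave 22 higher and 23 lower there, against 30 and 20. Neonatal against 15.5 dpc (1530) gave 3699, 2975, 5831 and 6044 with the replicate block, additive fit, neonatal block and both. The 15.5 against 13.5 dpc count (684) gave 1087 without a filter, 453 with the 60th percentile, 1593, 1394, 2824 and 3092 with the same 4 fits, and 2162 with neonatal replicate 2 alone. Same direction at 13.5 dpc was 80.77% with the neonatal block and 80.95% with replicate 2 alone. Lists past the test went from 6, 9, 12 and 15 to 1, 4, 0 and 0 with an estimated correlation. The gene mean counts genes and leaves out probe sets with no gene or several genes. The reported fit called 7 named genes for the parental mean, 2 for cortex, 3 for cerebellum and 2 for 15.5 dpc brain. Fewer probe sets were tested under the stricter filter and without _x_ and _s_ sets. For the other moves the cause was not tested. The planned replicate block gave 21, 12, 18, 11 and 0 for the parental results. Leaving out 1 array gave 14 to 20 for the parental mean, 10 to 16 for cortex (16 without cortex PatDp7 replicate 2), 10 to 15 for cerebellum, 10 to 12 at 15.5 dpc and 0 to 1 for the interaction (1 without cerebellum PatDp7 replicate 2). Cortex against cerebellum gave 29 to 43: 29 and 33 without cortex MatDp7 replicates 1 and 2, 31 and 32 without cerebellum MatDp7 replicates 1 and 2, and 32 without cerebellum PatDp7 replicate 1. Neonatal against 15.5 dpc gave 177 to 2076: 920 without cortex MatDp7 replicate 1, 886 without cerebellum MatDp7 replicate 1, 179 and 676 without 15.5 dpc MatDp7 replicates 1 and 2, and 263 and 177 without 15.5 dpc PatDp7 replicates 1 and 2. The 15.5 against 13.5 dpc count gave 174 to 748: 408 and 228 without MatDp7 replicates 1 and 2, and 174 and 278 without PatDp7 replicates 1 and 2. Same direction ranged from 85 to 100% and the chromosome 7 share from 83.33 to 100%. Detection calls were not used here, so signal over background was set by the filter alone.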

Other observations

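Other tissue lists also shifted between ages. At 15.5 dpc against 13.5 dpc, choroid plexus and ependymal genes were higher for 3 of 10, with Kcne2, a potassium channel subunit gene, at 1.66 ± 0.275 and Foxj1, a regulator of motile cilia, at 1.20 ± 0.288 (limma adjusted p = 0.013 and 0.049; camera adjusted p = 0.0253, adjusted p = 0.35 with an estimated correlation). Progenitor genes were higher for 3 of 19, with Sox2 at 1.06 ± 0.175 and Fabp7 at 1.10 ± 0.25 (0.0126 and 0.0398; camera adjusted p = 0.0395, adjusted p = 0.453 with an estimated correlation). Cholesterol synthesis genes were higher for 1 of 14, Msmo1, a sterol oxidase gene, at 1.43 ± 0.304 (0.033; camera adjusted p = 0.01, adjusted p = 0.423 with an estimated correlation). Ribosomal protein genes were lower in neonatal regions than at 15.5 dpc for 3 of 12, with Rpl35 at -0.62 ± 0.134 (0.0223; camera adjusted p = 0.0034, adjusted p = 0.448 with an estimated correlation).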
